A study of Mus musculus with 16 samples.

How the data were processed

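Gene expression was measured on 16 Illumina mouse bead arrays, each hybridised with labelled cRNA made from the total RNA of 1 sample. Per the labels, the samples were mouse embryonic stem cells with intact Rest (control, REST +/+) or without it (knockout, REST -/-), kept undifferentiated (day 0) or collected as embryoid bodies after 3, 6 or 9 days of differentiation, with 2 arrays for each of the 8 groups. REST is a repressor that binds a DNA element near many neuronal genes and recruits chromatin-modifying cofactors. Embryoid bodies are cell aggregates that form the early germ layers once leukemia inhibitory factor, which holds stem cells undifferentiated, is withdrawn. The labels number the arrays of a group but do not state that these came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. One knockout and one control genotype were compared, so that a difference between the cell lines and an effect of the deletion cannot be told apart.

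Per the file headers, the deposited table held, for each of 25697 probes and each array, an intensity that was not normalized between arrays and a detection p-value. The deposited intensity values had the background already subtracted, so that 25.5% to 28.0% of them per array lay below 0. The steps of the deposited p-value were those that a comparison with 798 negative control probes gives. A second table held intensity values that the authors had quantile normalized, as judged from the values. Each column kept the rank order of its array. The columns had nearly the same distribution on a linear scale, with medians from 26.8 to 27.1. The scanner software and the tool used for that step are not given in the sources used here. This second table served as an alternative only.

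Intensities were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (with statmod 1.5.0), which fits normexp with negative control means and variances inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A fold change is therefore on the log2(value + 16) scale and understates the change of dim genes. Probes were kept when the detection p-value was below 0.01 in both arrays of at least 1 group, which left 10241 probes. The probe annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719, which are unnamed here. The symbols were checked through Entrez identifiers, which matched 23962 probes in the RefSeq gene table, and 0 symbols changed. Among the detected probes 9627 had a gene and 614 were unnamed. For each gene the probe with the highest mean over the 16 arrays was used, giving 7505 genes, of which 1651 had 2 or more detected probes. Chromosomes and start positions of genes were taken from the mouse RefSeq gene table. The positions served to pick the genes nearest to Rest by distance and to order genes along chromosome 11.

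A linear model with 1 mean per group was fitted to all 16 arrays with lmFit and eBayes, with 8 residual degrees of freedom and 6.40 prior degrees of freedom. The 14 comparisons were knockout minus control at each of the 4 days and averaged over the days with equal weights, each later day minus day 0 within each genotype, and the difference between the genotypes in each of these changes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 7505 genes, separately per comparison, and every adjusted p of a gene below is from this limma test. Signs are knockout minus control unless stated. Errors given with log2 fold changes are the standard errors of limma's moderated fit, with 2 arrays per group. Where none of a gene's probes was detected on any array of a group, the fold is given as a lower bound: the mean of the brighter group against, per array, the higher of the lowest normalized value among detected probes and the probe's own value. A difference in change between the genotypes that draws on such a group has no such bound, and a size given for it is a fitted value that depends on the background. Medians of lists were also computed with such genes at their bound.

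In total 22 gene lists were written before the data were examined: REST targets, REST cofactors, pluripotency, primed epiblast, primitive streak and mesendoderm, cardiac regulators, cardiac contractile genes, primitive and visceral endoderm, basement membrane, neural ectoderm, blood and endothelium, mesenchyme and smooth muscle, trophoblast, the Wnt and the BMP, nodal and TGF-beta pathways, Hox genes, imprinted genes, hypoxia and glycolysis, p53 and apoptosis, cell cycle, ribosomal and housekeeping genes, and Y-linked genes with Xist. The last had 1 member tested and was left out, since at least 5 were required. The other 21 were tested with limma's camera, a test of whether the genes of a list are ranked higher or lower than other genes, with a preset correlation between genes of 0.01, adjusted over the 294 tests of 21 lists and 14 comparisons. Camera with an estimated correlation and the rotation test fry, which asks whether the genes of a list move on balance 1 way, were run as alternatives. Of 98 calls, 16 held with an estimated correlation. Among the genotype comparisons these were the 5 calls of the REST target list alone.

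Genes named in the text were fixed by a rule before the data were examined. For each genotype comparison these were Rest, the 6 largest rises and 6 largest falls past the threshold in which the arrays of the genotypes did not overlap, up to 3 called members of each list with the smallest adjusted p, and a fixed set of lineage genes whether or not they passed. For day 9 against day 0 and for the differences between genotypes in change, the 4 largest of each sign and the same fixed set were taken. Predicted genes and unnamed probes were passed over among the largest changes. Genes named outside this rule are said to be chosen after their values were seen.

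The fit was tested on simulated arrays with the spread of the real ones, in which both genotypes had the control means of each day. The noise was drawn for each gene on its own, so that errors shared between genes were not simulated. For the genotype comparison at day 3, with 7505 genes, planted changes of 0.5 on the log2 scale were called for 8 of 50 genes, of 1 for 46 of 50, and of 2 and 3 for 50 of 50 each, beside 5 of 7305 unchanged genes. The simulated comparisons at days 0, 6 and 9, which held no change, gave 0 called genes each. The number of arrays limits the precision.

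Alternatives were quantile normalization without background correction (values below 1 set to 1), median centring in place of quantile normalization, the authors' processed values on the log2 scale, no filter and a stricter filter on dim probes (detected on at least 8 of 16 arrays), the mean of a gene's detected probes, eBayes with trend and robust options, the replicate number as a block, fits of only the 4 arrays compared, a minimum of 2-fold, and leaving out each array in turn. The authors' values with 16 added before log2, and a crossed replicate block, were added after the data were seen. The alternative without background correction also left out the offset of 16, so that its results cannot be put down to background correction alone. The authors' log2 values had no offset either. With an array left out, the filter on dim probes was looser, since detection on the 1 array left in that group was then enough. A block for the slide could not be run, since neither the labels nor the column names give one.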

Results

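The series compared mouse embryonic stem cells lacking the transcriptional repressor REST with control cells through early differentiation, and its title places the question in the commitment of stem cells to the cardiac lineage. RNA from undifferentiated cells and from embryoid bodies of days 3, 6 and 9 was hybridised to 16 bead arrays, 2 for each genotype and day. Between 6300 probes (control day 0 replicate 2) and 9045 probes (knockout day 9 replicate 1) were detected per array, and the median intensity lay between 22.5 and 31.9. Arrays of a group correlated across genes with Pearson's r of 0.982 to 0.992. The first principal component, with 63.9% of the variance, followed the day of differentiation, and the second, with 18.5%, set day 3 apart. At day 3 the knockout arrays lay closer to day 0 on this component (31.6 and 34.9) than the control arrays (40.9 and 44.2). Control day 6 replicate 1 stood apart from the other 3 day 6 arrays on the first component, at 45.4 against 34.8 to 35.9.

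**Figure D1:**
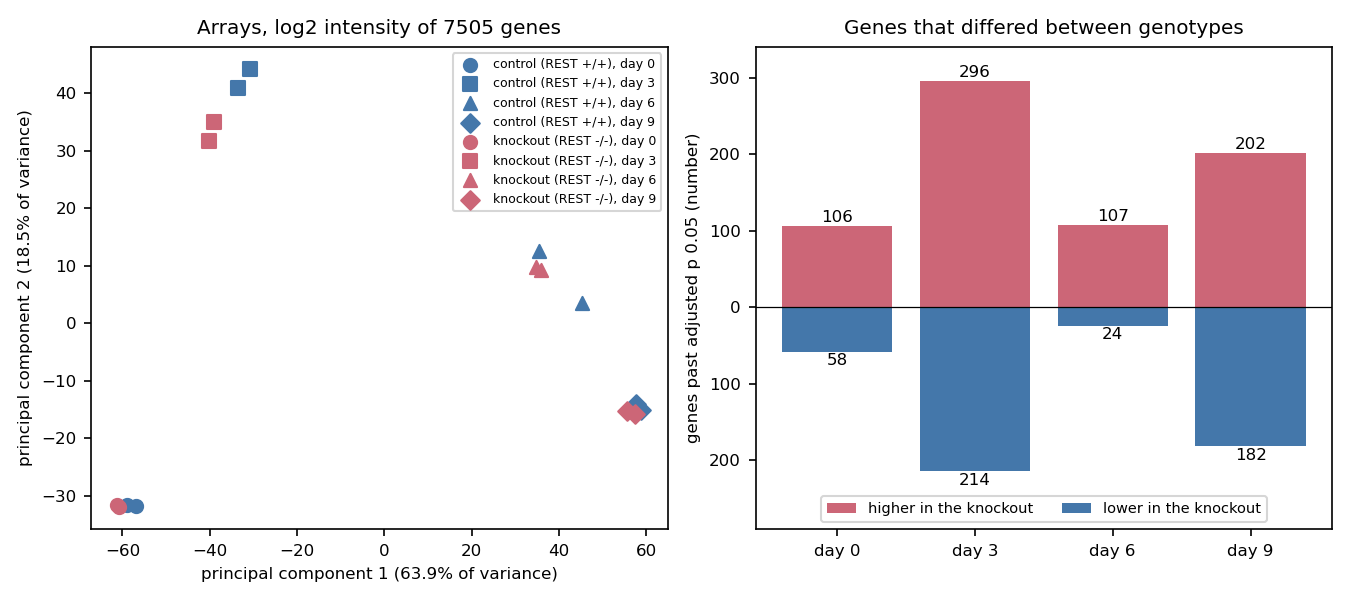
Left, the 16 arrays on the first 2 principal components of log2 intensity (colour, genotype; symbol, day), in which day separated the arrays more than genotype. Right, the number of genes past an adjusted p of 0.05 between genotypes on each day, largest at day 3 with 296 higher and 214 lower in the knockout.

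Rest itself, the deleted gene, could not be used to check the labels. Its single probe was not detected on any array: the highest intensity was 44.0, on control day 0 replicate 2, with a detection p of 0.0276. On the 8 control arrays the probe read between 4.00 and 44.0, and on the 8 knockout arrays between 1.26 and 32.0. With no filter on dim probes, Rest differed by a log2 fold change of -0.23 ± 0.07 averaged over the days (adjusted p = 0.0904), by -0.31 at day 0 (adjusted p = 0.435) and by -0.33 at day 3 (adjusted p = 0.310), so that no difference passed the threshold. Where the probe lies relative to the deleted part is not given in the sources used here.

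Genes known as REST targets were higher in the knockout on every day. The list held 57 genes, of which 51 were on the array and 30 passed the detection filter. Of the 30 listed targets tested, 16 rose at day 0, 21 at day 3, 21 at day 6 and 22 at day 9, and none fell. Targets detected in the knockout alone, such as Disp2 and Gdap1, passed the filter through their rise. The counts among tested targets therefore favour rises. Adjusted over the list alone, the counts were 20, 23, 23 and 24. The list's median log2 fold change was 0.88 at day 0, 1.15 at day 3, 2.29 at day 6 and highest at day 9, or 0.37, 0.59, 1.43 and 1.82 with undetected genes at their bound. Celsr3, a cadherin of neuronal wiring, rose by 2.85 ± 0.14 on the log2 scale at day 0 and was at least 16.8-fold higher at day 9. Disp2, a relative of the hedgehog release factor dispatched, was at least 1.75-fold higher at day 0, at least 11.7-fold higher at day 6 and at least 20.5-fold higher at day 9. Gdap1, a mitochondrial protein of neurons mutated in Charcot-Marie-Tooth disease, was at least 3.30-fold, 8.85-fold and 15.2-fold higher at days 3, 6 and 9. Scg3, a secretory granule protein, was at least 2.96-fold higher at day 0 (adjusted p = 1.55e-09). Syt4, a synaptotagmin of vesicle release, rose by 2.44 ± 0.16 at day 0 and was at least 4.90-fold, 2.92-fold and 5.38-fold higher at days 3, 6 and 9. Camera called the list on each day, with adjusted p values from 2.44e-66 to 3.81e-32. The call held with an estimated correlation, with adjusted p from 1.45e-05 to 6.48e-05, and under each of the 28 settings run.

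**Figure D2:**
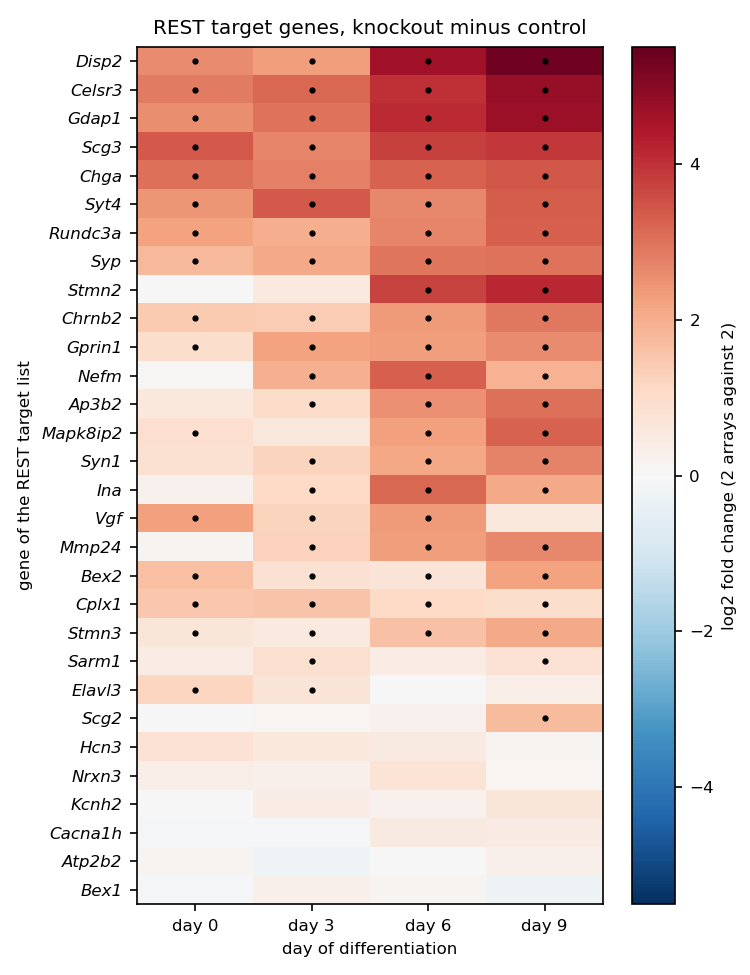
Log2 fold change, knockout minus control, of the 30 REST targets tested on each day (2 arrays against 2), with dots on genes past an adjusted p of 0.05. Disp2, Celsr3 and Gdap1 stand at the top with dots on all days, while Stmn2 is marked at days 6 and 9 alone.

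Stmn2, a microtubule regulator of growing neurites, is a REST target with a different course. In control cells it fell by at least 10.2-fold from day 0 to day 9, with an adjusted p of 1.33e-11, and was not detected at days 6 and 9. In the knockout it changed by -0.15 ± 0.16 over the same time (adjusted p = 0.423). It differed between genotypes by 0.04 ± 0.16 at day 0 (adjusted p = 0.943) and by 0.55 ± 0.16 at day 3 (adjusted p = 0.0501), and was at least 7.79-fold higher in the knockout at day 6 and at least 9.44-fold higher at day 9. The change of Stmn2 from day 0 differed between the genotypes at day 6 (adjusted p = 4.00e-07) and at day 9 (adjusted p = 3.77e-08). Without background correction the day 6 difference in change was not called (adjusted p = 0.164).

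At day 0, in undifferentiated cells, 106 genes were higher and 58 lower in the knockout. Mest, an imprinted hydrolase of mesoderm, rose by 3.28 ± 0.13 with both of its other probes higher as well, and Vstm2l, a neuronal immunoglobulin-domain protein, was at least 4.19-fold higher. Chga, the granule protein chromogranin A, was at least 4.56-fold higher. Among the largest falls, Igf2, an imprinted growth factor, changed by -2.67 ± 0.19 (adjusted p = 7.84e-07) and Krt8, a keratin of simple epithelia, by -2.16 ± 0.16 (adjusted p = 7.84e-07). Its partner Krt18 was at least 1.28-fold lower, Bmp1, a procollagen protease, at least 2.32-fold and Phldb2, a protein of cell adhesion sites, at least 2.19-fold. The pluripotency regulators Pou5f1, Nanog, Sox2 and Zfp42 differed by 0.01, 0.27, 0.14 and -0.23, with adjusted p between 0.706 and 0.996.

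Besides the REST targets, camera called 2 lists at day 0. Igf2, Krt8 and Krt18 made up the 3 falls among 10 trophoblast genes, again 3 when adjusted over the list alone (median -0.07, adjusted p = 0.0200, and adjusted p = 0.117 with an estimated correlation). These 3 are also expressed outside trophoblast, in epithelia and mesoderm. None of 23 basement membrane genes was called singly, also none adjusted over the list alone, while their median was -0.28 (adjusted p = 1.96e-04, and adjusted p = 0.132 with an estimated correlation). Of the genes called, 64.6% were higher in the knockout. That share was 84.3% with median centring and 50% without background correction. The count moved with single arrays, with 282 genes without control replicate 1, 107 without control replicate 2, and 88 and 71 without knockout replicates 1 and 2. Krt18 lost its call without 3 of these 4 arrays, and the trophoblast list lost its own without control replicate 1.

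With all 16 arrays fitted, the comparison was largest at day 3, with 296 genes higher and 214 lower in the knockout. Genes of the primitive streak and early mesoderm were lower at this day. Mesp1, which marks the earliest cardiac progenitors, changed by -3.48 ± 0.36 (adjusted p = 1.60e-05), and Lhx1, a regulator of anterior mesendoderm, by -3.45 ± 0.35 (adjusted p = 1.50e-05). Mixl1, a streak homeobox gene, changed by -1.61 ± 0.28 (adjusted p = 0.00192), Frzb, a secreted Wnt inhibitor, by -2.96 ± 0.28, Tbx6, a regulator of paraxial mesoderm, was at least 3.98-fold lower, and Pdgfra, a receptor of early mesoderm, at least 2.62-fold. Of 16 streak and mesendoderm genes tested, 12 fell and 1 rose, the same counts adjusted over the list alone, and the median was -1.43. The gene that rose was Nodal, an inducer of the streak, at 0.90 (adjusted p = 0.0254), chosen here after its value was seen. Camera gave an adjusted p of 1.81e-14 for the list, and adjusted p = 0.0620 with an estimated correlation.

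Regulators of heart and endoderm and receptors of the blood and vessel lineage were also among the falls at day 3. Sox17, a regulator of endoderm, was at least 4.02-fold lower and Gata6, which acts in heart and endoderm, changed by -3.28 ± 0.37 (adjusted p = 4.39e-05). Kdr, the VEGF receptor of blood and vessel progenitors, was at least 3.28-fold lower, Gata2, a regulator of blood stem cells, at least 1.78-fold, and Lmo2, its partner, at least 1.95-fold. The list of 26 blood and endothelium genes had 4 falls and 1 rise, the same adjusted over the list alone, and was not called (adjusted p = 0.425). Of 15 cardiac regulators, 3 fell and 1 rose, the same adjusted over the list alone (median -0.17, adjusted p = 0.0133, and adjusted p = 0.114 with an estimated correlation). With undetected genes at their bound that median was 0. Of 20 genes of the BMP, nodal and TGF-beta pathways, 5 fell and 2 rose (9 and 3 adjusted over the list alone), with a median of -0.33 (adjusted p = 0.00149, and adjusted p = 0.233 with an estimated correlation). The 5 included Chrd, a BMP antagonist, at -1.07 ± 0.17, and Msx1, a BMP-responsive homeobox gene, at -1.39 ± 0.22. Lmo1, a nuclear adaptor protein, changed by -3.09 ± 0.22, and Sema6d, a guidance protein, was at least 3.91-fold lower.

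Some genes of the earlier epiblast state were higher in the knockout at day 3, while others did not pass. Pou3f1, a marker of the primed epiblast, rose by 2.15 ± 0.27, and 6 of 13 primed epiblast genes rose with none falling (7 and 2 adjusted over the list alone), at a median of 0.64 (adjusted p = 0.00388, and adjusted p = 0.128 with an estimated correlation). Of 28 pluripotency genes, 6 rose and 1 fell (11 and 3 adjusted over the list alone), at a median of 0.38 (adjusted p = 9.93e-04, and adjusted p = 0.396 with an estimated correlation). Sox2 rose by 0.92 ± 0.22 and Dnmt3l, a cofactor of DNA methylation, by 1.00 ± 0.16, whereas Pou5f1 differed by -0.01 ± 0.16 (adjusted p = 0.983). Of 25 genes of hypoxia and glycolysis, 6 rose and 2 fell (8 and 2 adjusted over the list alone), at a median of 0.27 (adjusted p = 0.00201, and adjusted p = 0.188 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, rose by 1.12 ± 0.22, and Aldoc, a brain aldolase, was at least 1.54-fold higher. The number of genes called fell to 213 without control replicate 1 and to 210 without knockout replicate 2. In the setting without background correction, which also left out the offset of 16, it was 255. There Mesp1 (adjusted p = 0.271), Lhx1, Kdr, Frzb, Mixl1, Pou3f1, Sox2 and Dnmt3l were not called, with the same direction. These losses cannot be put down to background correction alone. The pluripotency, primed epiblast and BMP lists then lost their calls, leaving 4 of 7. The authors' log2 values also left 4, whereas with 16 added to them 7 lists were called.

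**Figure D3:**
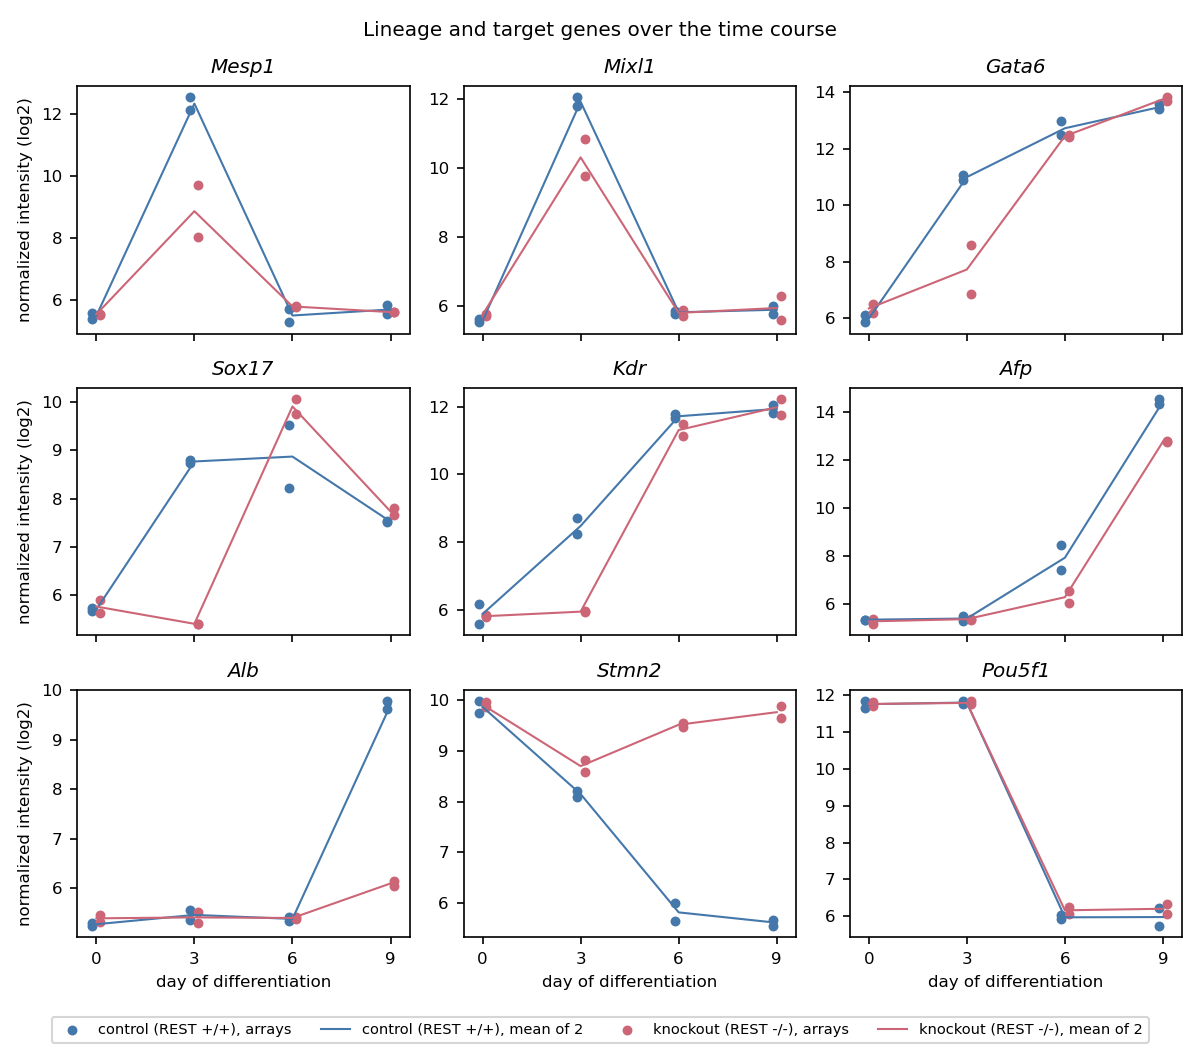
Normalized log2 intensity of 9 genes on each array (dots) and group means of 2 arrays (lines) over the 4 days. Mesp1, Mixl1, Gata6, Sox17 and Kdr are lower in the knockout at day 3, Afp at days 6 and 9 and Alb at day 9, Stmn2 is higher at days 6 and 9, and the Pou5f1 lines overlap.

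At day 6, 107 genes were higher and 24 lower in the knockout, with REST targets leading the rises. Celf3, a neuronal RNA-binding protein, was at least 10.9-fold higher. Apom, an apolipoprotein, rose by 1.91 ± 0.23, Fgb, the fibrinogen beta chain, was at least 1.53-fold higher and Pga5, a pepsinogen, at least 2.58-fold, while Afp, the fetal plasma protein alpha-fetoprotein, changed by -1.65 ± 0.25 (adjusted p = 0.00128). These made up the 3 rises and 1 fall among 25 genes of primitive and visceral endoderm (13 and 1 adjusted over the list alone), whose median was 0.47 (adjusted p = 9.19e-07, and adjusted p = 0.0884 with an estimated correlation). Mesp1 and Mixl1 were not detected in either genotype at this day, and Sox17 differed by 1.04 ± 0.28 (adjusted p = 0.0944). The streak list as a whole was ranked higher, with 1 rise, that of Fgf8 (2 adjusted over the list alone), and a median of 0.32 (adjusted p = 0.0310, and adjusted p = 0.538 with an estimated correlation).

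Of the other lists called at day 6, pluripotency had 2 rises among 28 genes (6 adjusted over the list alone; median 0.15, adjusted p = 0.00142, and adjusted p = 0.420 with an estimated correlation). Dppa5a, an RNA-binding protein of stem cells, rose by 1.60 ± 0.27. Basement membrane genes had no single call (4 falls adjusted over the list alone; median -0.30, adjusted p = 0.00123, and adjusted p = 0.193 with an estimated correlation). Mesenchyme and smooth muscle genes had 1 rise, Mest, and 1 fall, Postn (1 and 3 adjusted over the list alone; median -0.26, adjusted p = 0.00320, and adjusted p = 0.281 with an estimated correlation). Blood and endothelium genes had no single call on either basis, adjusted over the list alone included, at a median of 0.25 (adjusted p = 0.00618, and adjusted p = 0.152 with an estimated correlation). BMP, nodal and TGF-beta genes had 1 rise (2 adjusted over the list alone; median 0.21, adjusted p = 0.00417, and adjusted p = 0.276 with an estimated correlation). Hypoxia and glycolysis genes had 1 rise, that of Ldha (2 adjusted over the list alone; median 0.21, adjusted p = 0.0218, and adjusted p = 0.281 with an estimated correlation). Nuak1, a stress-responsive kinase, was at least 1.69-fold lower, but without the filter on dim probes another probe represented the gene and gave 0.28 (adjusted p = 0.631). Without control replicate 2 the count rose to 279 genes, of which 58.4% were higher in the knockout against 81.7% with all arrays, and the calls of the blood and the hypoxia lists ended. Without control replicate 1, the array that stood apart, 5 of the 9 lists were called, and the streak, basement membrane, mesenchyme and BMP lists were not. The calls of Rarb, a retinoic acid receptor, and Nepn, a matrix protein, ended without that array as well. Without background correction 7 of the 9 lists were called, the blood and mesenchyme lists not.

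At day 9, 202 genes were higher and 182 lower in the knockout, and several liver-type plasma proteins were lower. Alb, serum albumin, was at least 8.97-fold lower (adjusted p = 1.00e-10). Itih2, a plasma protein that stabilizes the hyaluronan matrix, changed by -2.64 ± 0.13, Ambp, a plasma protease inhibitor, by -2.42 ± 0.13, Apoa2, an apolipoprotein, by -2.23 ± 0.16, Fgb by -1.99 ± 0.16 and Afp by -1.67 ± 0.25. The 25 genes of primitive and visceral endoderm went both ways, with 6 falls and 2 rises (7 and 4 adjusted over the list alone), at a median of -0.08 (adjusted p = 0.0488, and adjusted p = 0.451 with an estimated correlation). That call was present under 9 of the 28 settings. Foxf2, a regulator of gut mesenchyme, changed by -2.20 ± 0.18 and Actg2, a smooth muscle actin, by -2.36 ± 0.29. Of 25 mesenchyme and smooth muscle genes, 3 fell, among them Lox, a collagen crosslinking enzyme, at -1.27 ± 0.17, and 1 rose, Mest (8 and 2 adjusted over the list alone; median -0.36, adjusted p = 0.00526, and adjusted p = 0.314 with an estimated correlation).

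Cardiac contractile genes were ranked lower at day 9. Of 18 tested, 2 fell, Nexn, an actin-binding protein of the sarcomere, at -0.66 ± 0.16 and Myl2, the ventricular myosin light chain, at -0.70 ± 0.18, and none rose (6 and 0 adjusted over the list alone). The list's median was -0.49 (adjusted p = 4.36e-04, and adjusted p = 0.358 with an estimated correlation). Both single calls ended with median centring, without background correction and without either control day 9 array. The heart muscle genes Myh6, Myl7 and Actc1 differed by -0.63 ± 0.22, -0.21 ± 0.66 and -0.95 ± 0.57, with adjusted p of 0.134, 0.919 and 0.446. Nkx2-5 and Gata4, regulators of the heart, and Sox1, of neural ectoderm, were below the filter, and the T (brachyury) and Tnnt2 genes were not analysed here. Of 23 basement membrane genes, 1 fell, Itga6, a laminin receptor chain (10 adjusted over the list alone; median -0.44, adjusted p = 2.69e-05, and adjusted p = 0.0967 with an estimated correlation). The laminin chains Lamb1 and Lamc1 differed by -0.50 ± 0.19 and -0.52 ± 0.19, with adjusted p of 0.177 and 0.153.

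Stem cell genes and neuronal genes were among the rises at day 9. Of 28 pluripotency genes 6 rose and none fell (9 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.00537, and adjusted p = 0.503 with an estimated correlation). Dppa5a rose by 1.78 ± 0.27, Lin28a, a regulator of microRNA processing, by 1.39 ± 0.24 and Nanog by 1.19 ± 0.26 (adjusted p = 0.0135), whereas Pou5f1 was not detected in either genotype. The list's call ended without knockout replicate 1 and with median centring. Vstm2l was at least 70.6-fold higher, Cbln4, a synapse organiser, at least 22.8-fold and Lrp11, a membrane protein of the brain, at least 17.1-fold. Gap43, of axon growth, and Map2, of dendrites, rose by 1.29 ± 0.17 and 1.28 ± 0.19. Hypoxia and glycolysis genes had 2 falls among 25 (3 adjusted over the list alone; median -0.20, adjusted p = 0.00995, and adjusted p = 0.233 with an estimated correlation). The count of 384 genes fell to 209 without control replicate 1, to 213 without control replicate 2 and to 225 without knockout replicate 2, and was 178 without background correction, where Itih2 (adjusted p = 0.187), Ambp, Apoa2, Actg2, Lox and Nanog were not called. The cardiac contractile, endoderm and mesenchyme lists then lost their calls, leaving 4 of 7. This setting also left out the offset of 16, and with 16 added to the authors' values 5 lists were called. The share of called genes higher in the knockout, 52.6%, was 80.9% with median centring and 64.0% without background correction.

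**Figure D4:**
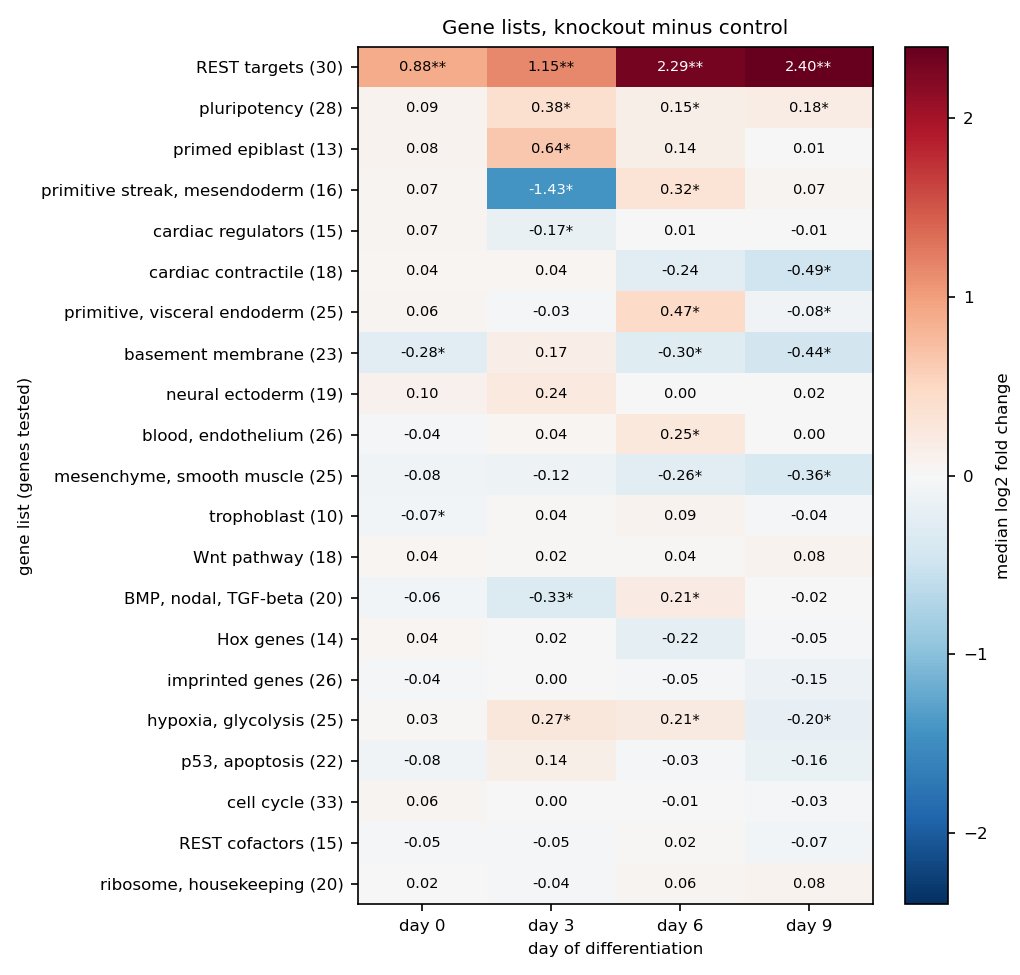
Median log2 fold change, knockout minus control, of the 21 gene lists tested on each day (number of genes in parentheses; colour and figure give the median). One asterisk marks lists called with the preset correlation and 2 those also called with an estimated correlation, which were the REST targets alone, and the streak list stands lowest at day 3 with -1.43.

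Of the 21 lists, 8 were called in none of the genotype comparisons. For neural ectoderm the median was at most 0.24 on the single days, and the rises included Neurod1, a neuronal differentiation factor, on each day (2.26 ± 0.23 at day 3). Its members moved both ways, and Dll3 changed by -1.68 ± 0.16 at day 3 (adjusted p = 7.18e-06). The Wnt pathway, Hox, imprinted, p53 and apoptosis, and cell cycle lists had medians from -0.22 to 0.14. REST cofactors and ribosomal and housekeeping genes had medians from -0.07 to 0.08 and no single gene called on any day.

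Averaged over the 4 days, 388 genes were higher and 381 lower in the knockout, from 8 arrays against 8. Mest rose by 3.18 ± 0.06, Neurod1 by 1.75 ± 0.11 and Nanog by 0.75 ± 0.13, while Phldb2 changed by -0.96 ± 0.08, Map4k4, a signalling kinase, by -0.88 ± 0.11, and Ccn1, a matrix signal, by -0.94 ± 0.09. Of 30 REST targets 25 rose (27 adjusted over the list alone; median 1.68, adjusted p = 3.81e-55, and adjusted p = 1.45e-05 with an estimated correlation). Pluripotency genes had 8 rises and no falls among 28 (13 and 1 adjusted over the list alone; median 0.23, adjusted p = 6.01e-06, and adjusted p = 0.233 with an estimated correlation). Mesenchyme and smooth muscle genes had 10 falls and 2 rises among 25 (13 and 2 adjusted over the list alone; median -0.27, adjusted p = 9.36e-05, and adjusted p = 0.192 with an estimated correlation), with Acta2, smooth muscle actin, at -0.60 ± 0.11. Basement membrane genes had 4 falls (7 adjusted over the list alone; median -0.16, adjusted p = 0.00142, and adjusted p = 0.193 with an estimated correlation), streak genes 6 (9 falls and 1 rise adjusted over the list alone; median -0.37, adjusted p = 0.00421, and adjusted p = 0.381 with an estimated correlation) and cardiac contractile genes 3 (5 falls and 2 rises adjusted over the list alone; median -0.20, adjusted p = 0.0250, and adjusted p = 0.591 with an estimated correlation). The call of the cardiac contractile list ended without control day 0 replicate 1 and without replicate 1 of either genotype at day 6. Without background correction its call and that of the streak list ended, leaving 4 of 6 lists, and the streak list turned its direction (adjusted p = 0.941). With median centring 1310 genes were called, 83.7% of them higher in the knockout against 50.5% here.

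Genes that differed on all 4 days were higher in the knockout in each case, with 35 genes up and 0 down. Of these 35, 13 were on the REST target list, among them Celsr3, Chga, Scg3, Stmn3, Syp and Syt4, while Mest, Vstm2l, Rell2, a TNF receptor binding protein, and Gnptg, an enzyme subunit of lysosomal sorting, were not. Stmn3, Syp and Gnptg are named here after their values were seen. Of 896 genes called on at least 1 day, 372 were called at day 3 alone and 225 at day 9 alone. The genotype log2 fold changes of different days, which share no array, correlated across genes with r from 0.28 (days 0 and 3, and days 3 and 9) to 0.58 (days 6 and 9). Days 6 and 9 shared 83 rises against 2.88 expected for independent lists, and 8 falls against 0.582. Days 3 and 9 shared 76 rises and 19 falls, and 19 further genes were called in opposite directions. These are correlations and overlaps across genes, which are not independent replicates.

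The genes of chromosome 11 stood higher in the knockout as a set. Their median genotype difference averaged over days was 0.109 on the log2 scale above that of all genes (649 genes, bootstrap 95% interval 0.0936 to 0.123), whereas the other 19 chromosomes with at least 175 genes tested lay between -0.0351 and 0.0188. The difference was 0.0567, 0.0877, 0.115 and 0.121 at days 0, 3, 6 and 9. All 8 knockout arrays lay above all 8 control arrays, at 0.0328 to 0.0768 against -0.0613 to -0.0203 from the mean of their day. Called genes made up 11.2% of chromosome 11 genes, against 10.2% of all genes and up to 13.1% on chromosome 18. This comparison of chromosomes was planned, and the values per array were computed after its result was seen. The bootstrap interval, like those below, was drawn over genes, which are not independent replicates, and leaves out the spread between arrays.

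**Figure D5:**
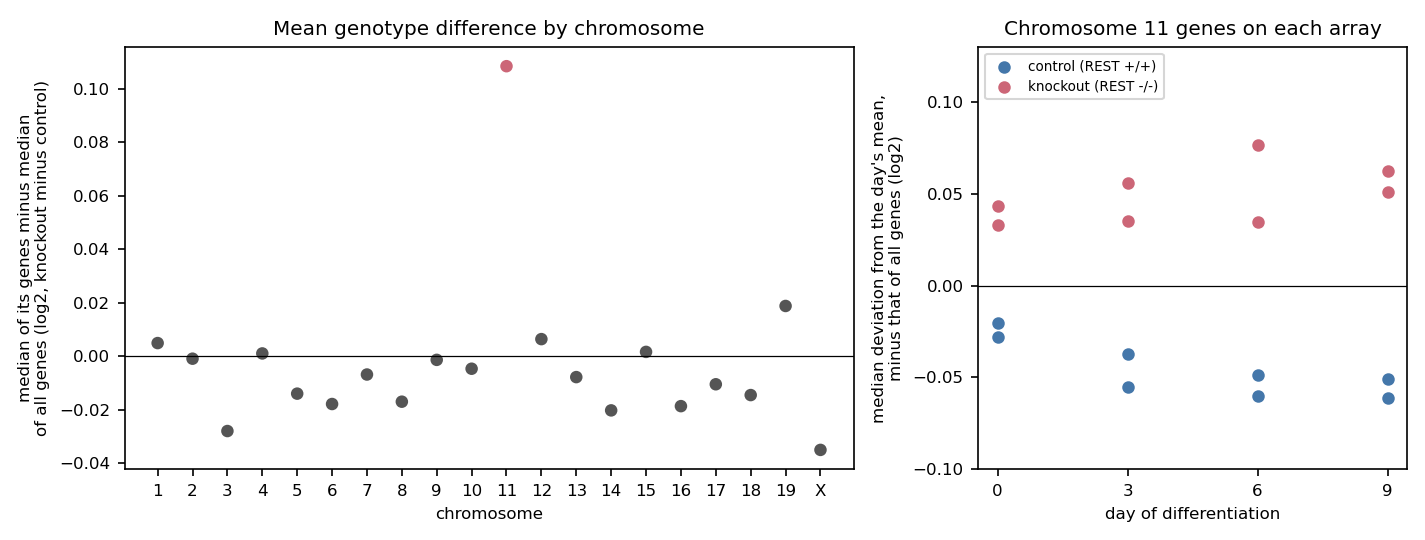
Left, the median genotype difference (log2, knockout minus control, mean over days) of the genes of each chromosome minus that of all genes, in which chromosome 11 stands at 0.109 and the others between -0.0351 and 0.0188. Right, the median deviation of chromosome 11 genes from the day's mean, minus that of all genes, on each of the 16 arrays.

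Differentiation itself changed most genes in both genotypes. From day 0 to day 9, 2642 genes rose and 2554 fell in control cells and 2656 rose and 2565 fell in the knockout. Pou5f1, the core pluripotency factor, was at least 37.2-fold lower at day 9 in controls and at least 37.3-fold lower in the knockout, and Tdgf1, a nodal co-receptor, was at least 221-fold lower in controls and fell by 7.03 on the log2 scale in the knockout. Col3a1, a fibrillar collagen, rose at least 429-fold in controls and at least 545-fold in the knockout, and Myl7, the atrial myosin light chain, at least 7.37-fold and 8.07-fold. Of 28 pluripotency genes 27 fell in controls and 26 in the knockout, at medians of -4.53 and -3.88 (adjusted p = 0.0884 for both with an estimated correlation). Of 18 cardiac contractile genes 15 rose and 1 fell in controls and 12 rose and 1 fell in the knockout (adjusted p = 0.398 and 0.544 with an estimated correlation). Of 25 mesenchyme and smooth muscle genes 23 rose and 1 fell in each genotype (adjusted p = 0.0752 and 0.0810 with an estimated correlation). The changes of the genotypes, which share no array, correlated across genes with r of 0.889 at day 3, 0.956 at day 6 and 0.953 at day 9. At day 3, 2814 genes were called in the same direction in both genotypes, against 896 expected for independent lists, and 17 in opposite directions. The counts from day 0 to day 3 were 2038 rises and 1829 falls in controls and 1847 and 1620 in the knockout, and to day 6 they were 2428 and 2300, and 2379 and 2244. With median centring the share of rises at day 3 was 69.8% against 52.7% in controls and 65.7% against 53.3% in the knockout, and at day 6 71.2% against 51.4% and 66.6% against 51.5%.

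The change from day 0 differed between the genotypes for 200 genes at day 3, 76 at day 6 and 169 at day 9. Without background correction 111 genes were called at day 3 and 82 at day 9. The day 3 count was 68 without control day 3 replicate 1, 85 without knockout day 3 replicate 2, and 100 and 87 without knockout day 0 replicates 1 and 2. The day 6 count was 146 without control day 6 replicate 2 and 47 without replicate 2 of the knockout at day 0 or day 6. At day 3 the rise of Mesp1 differed by -3.53 ± 0.50 on the log2 scale (adjusted p = 0.00154), with Gata6 at -3.64 ± 0.52 and Lmo1 at -3.47 ± 0.31, and Sox17, undetected in the knockout at day 3, was called as lower (adjusted p = 2.80e-04). Itga3, a laminin receptor chain, differed the other way, by 2.23 ± 0.32. At day 6 the neuronal genes Celf3 (adjusted p = 4.00e-07), Nefm, a neurofilament (adjusted p = 1.02e-06), and Ina, an internexin (adjusted p = 2.91e-06), were called as higher, all 3 undetected in controls at that day. Scg5, a granule chaperone detected at day 0 in the knockout alone, was called as lower (adjusted p = 3.02e-05). At day 9 Itih2 differed by -2.73 ± 0.18, Actg2 by -2.48 ± 0.41 and Apoa2 by -2.37 ± 0.23. Cbln4, undetected in controls, was called as higher (adjusted p = 2.37e-08) and Alb, undetected in the knockout, as lower (adjusted p = 3.52e-08). Apart from Itga3 and Ina, the genes named here were undetected at day 0 in at least 1 genotype, so that the sizes given are fitted values near the background. These 3 comparisons share the day 0 arrays and were not set against one another.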

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

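The results of this part were picked out for 2 reasons: the effect of the genotype differed between days in a test of that difference itself, or a signal appeared in probes that the comparisons of genes leave out. All tests on the secreted proteins of day 9 below were chosen only after the result was seen. Groups of 2 arrays are too small for a test of single outlying arrays.

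The change from day 0 differed between the genotypes for 200 genes at day 3, 76 at day 6 and 169 at day 9, with 68 to 241, 47 to 146 and 116 to 190 when 1 array was left out. Among single genes fixed beforehand, the day 3 differences were -3.53 for Mesp1, -3.43 for Sox17, -1.78 for Mixl1 and 0.93 for Syt4, the last with an adjusted p of 0.0426. Stmn2 differed by 3.66 at day 6 and by 4.12 at day 9, and Afp by -1.60 at day 9. These are fitted values and no measured folds, since each of these genes was undetected in at least 1 group compared: Mesp1, Mixl1, Sox17 and Afp at day 0, Sox17 also in the knockout at day 3, Syt4 in controls at day 3 and Stmn2 in controls at days 6 and 9. Without 1 of several arrays the calls of Mixl1, Syt4 and Afp ended.

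For the gene lists, the median differences at day 3 were -1.59 for primitive streak genes (9 of 16 called, all lower; adjusted p = 0.0723 with an estimated correlation), -0.38 for cardiac regulators, -0.24 for BMP, nodal and TGF-beta genes, 0.44 for primed epiblast, 0.46 for basement membrane, 0.25 for trophoblast and 0.31 for hypoxia and glycolysis. At day 6 they were 0.49 for REST targets, 0.64 for primitive and visceral endoderm, 0.17 for blood and endothelium, 0.23 for trophoblast and 0.30 for BMP, nodal and TGF-beta genes. At day 9 they were 1.12 for REST targets, -0.46 for cardiac contractile genes, -0.11 for endoderm and -0.33 for hypoxia and glycolysis. With an estimated correlation the REST targets alone remained called, with adjusted p of 6.38e-04 at day 6 and 2.71e-04 at day 9.

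Of the 614 detected probes that had no gene, 60 differed between genotypes averaged over days, 28 higher and 32 lower in the knockout. That was 9.77% of them, beside 9.33% of the detected probes with a gene.

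The lower primitive streak genes at day 3 were set against 3 explanations other than a specific effect. If all changes of the knockout were reduced by the same share, streak genes would lag no more than others. The slope of knockout on control change was 0.720 for them and 0.881 for 1258 other changed genes. The difference was -0.161 (bootstrap 95% interval -0.294 to -0.0504). This argues against an equal reduction of all changes. A general delay stays open, since it need not reduce every change equally. The slope of the other genes also lay below 1 (0.862 to 0.901). A delay in this lineage alone stays open too. Leaving out any 1 day 3 array left the list's median at -1.13 or lower, and 3 other normalizations left it at -1.44 or lower, so neither a single array nor the scaling accounts for it. A weaker or later formation of mesendoderm in these knockout cells is therefore a hypothesis, and whether it follows from Rest or from the line was not tested.

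The lower liver-type secreted proteins at day 9 may reflect fewer endoderm cells or lower expression in them. The 12 secreted proteins of the endoderm list had a median of -0.594 and its 5 regulators and receptors one of -0.0293, a difference of -0.565 with an interval from -2.05 to 0.675, so that these cannot be told apart with 5 genes. Spink1, a secreted protease inhibitor chosen after its value was seen, rose by 1.56, so that the members moved both ways. Without 1 day 9 array the median of the secreted proteins was as high as -0.481, past the bound of -0.5 that had been set, so that a share of the pattern could rest on 1 array. Alb, Fgb and Afp were each called at day 9 under the 25 settings that tested them, and the stricter filter left them out.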

How the results depend on the processing

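The number of genes called moved with the background correction, the scaling, the arrays fitted together and single arrays. The slide alternative could not be run, since no slide is given. The alternatives with 16 added to the authors' values and with a crossed block were chosen after seeing the data. Without background correction and with the authors' log2 values, the counts were 255 and 254 at day 3, 178 and 178 at day 9, 467 and 468 for the mean over days, 111 and 112 for the difference in change at day 3 and 82 and 81 at day 9. With 16 added to the authors' values the last 2 were 122 and 103. Of 381 results for named genes 273 kept their call or its absence without background correction, 105 lost their call, 2 gained one and 1 turned. The authors' log2 values gave the same numbers. With 16 added to the authors' values 330 kept their call or its absence, 50 lost their call, 1 gained one and none turned. Leaving out the offset, with values below 1 set to 1, thus carried part of the losses. Median centring gave 1310 genes for the mean over days (1097 higher, 213 lower), and moved the median of all genes by 0.13 at day 0, 0.17 at day 9 and 0.10 in the mean, and in the changes from day 0 by 0.23 and 0.33 at days 3 and 6 in controls and 0.16 and 0.25 in the knockout. The stricter filter, with fewer genes tested, gave 82 genes at day 6 and 229 at day 9, and 46 and 73 for the differences in change at these days. Fits of only the 4 arrays compared gave 36, 294 and 76 genes at days 0, 3 and 6. At least 2-fold changes numbered 59, 196, 87 and 164 at days 0, 3, 6 and 9, and 65 for the mean. With an estimated correlation 16 of 98 list calls held. Without background correction 5, 3 and 2 lists were called for the differences in change at days 3, 6 and 9, against 7, 5 and 4, and the authors' log2 values gave the same numbers. Fry called 142 lists, most of them in the changes from day 0. It called 3, 8, 7, 5 and 6 lists at days 0, 3, 6 and 9 and in the mean over days. Camera called 3, 7, 9, 7 and 6 there. Fry did not call pluripotency at days 3, 6 and 9 or mesenchyme genes at days 6 and 9 and in the mean. Cardiac contractile genes at day 9 and in the mean were not called either. Nor were streak genes at day 6 and in the mean, or BMP genes at day 6. The mean correlation of the genotype effect between days, 0.364, was 0.320 without background correction and with the authors' log2 values, and 0.368 with 16 added to the latter. It was 0.305 with no filter and 0.399 with the stricter filter.

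Some results turned their direction, and apart from Nuak1, read below as a change of probe, the cause was not tested. The endoderm list turned under the stricter filter at day 9 (adjusted p = 0.0705) and in the difference in change at day 9 (adjusted p = 0.0676). The streak list in the mean over days turned without background correction (adjusted p = 0.941) and with the authors' log2 values (adjusted p = 0.943). Wnt8a in the mean became -0.0661 and -0.0333 there. With 16 added to the authors' values Wnt8a did not turn, while the streak list was still not called in the mean. Nuak1 at day 6 became 0.28 with no filter, where another probe represents it. With 1 array left out Nuak1 lay between -2.25 and 0.29, the latter without control day 9 replicate 1. That array is not part of the day 6 comparison. Without it, detection on the 1 control day 9 array left was enough for a probe to pass the filter. The value lay close to that with no filter, so that it is read as a change of probe and not as an effect of that array.

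Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 71 to 282 genes at day 0, 210 to 571 at day 3, 88 to 279 at day 6, 209 to 425 at day 9 and 575 to 938 for the mean. The differences in change gave 68 to 241, 47 to 146 and 116 to 190 at days 3, 6 and 9. The changes from day 0 gave 3115 to 3912, 4182 to 4744 and 4708 to 5250 in controls and 2740 to 3675, 4006 to 4808 and 4772 to 5398 in the knockout. The mean correlation was 0.327 to 0.369 and the lists called 90 to 99. At day 0 the count was 282 and 107 without control replicates 1 and 2, and 88 and 71 without knockout replicates 1 and 2. At day 3 it was 213 without control replicate 1 and 210 without knockout replicate 2, at day 6 it was 279 without control replicate 2, and at day 9 it was 209 and 213 without control replicates 1 and 2 and 225 without knockout replicate 2.

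With a replicate block the counts were 145, 498, 124 and 347 at days 0, 3, 6 and 9 and 726 for the mean. A crossed block gave 152, 488, 124, 364 and 735. Arrays of the same number in the 2 genotypes deviated from their groups with r of -0.12, 0.06, -0.18 and 0.07 at the 4 days, so that the numbers do not pair the arrays. Dim signal limits the rest: Rest itself lay below detection, and folds of dim genes are understated.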

Other observations

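The tests on the part of chromosome 11, the values for differences of at least 0.5 and the count of these genes near Rest were chosen only after the results were seen, and the single genes named here were chosen after their values were seen. Outside the REST target list, 182 genes called in the mean over days differed in the same direction on all 4 days, each day by 0.5 to 2 times that mean, 87 higher and 95 lower in the knockout. This range is wide: for 9 of them the change from day 0 differed between the genotypes, among them Vstm2l, undetected in controls at days 0, 3 and 9. Diras1, a small GTPase of the brain, was detected on each knockout array and no control array. Gnptg, a subunit that tags lysosomal enzymes, was higher by 1.78 averaged over days, Stx1a, a syntaxin of synaptic release, by 1.34, and Asns, asparagine synthetase, by 0.91. Mest, at 3.18, belonged to this set. Map4k4, a signalling kinase, differed by -0.88.

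Such lasting differences may come from the lines and not from the loss of Rest, and 3 ways were tested. Genes near Rest, which could carry the genetic background of the edited cells, were called more often: 9 of the 40 tested genes nearest to it against 10.2% elsewhere, a ratio of 2.21 (Fisher exact p = 0.0177). The planned test also asked for a ratio of at least 3, which was not reached, so that it left this explanation open. It took neighbouring genes as independent. It counted every gene called in the mean, and 6 of the 9 are outside the 182, among them Kdr and Pdgfra, which fell at day 3. Noa1, a mitochondrial GTPase at 0.81, was 1 of the 3 that belong to the 182, or 7.5% of the 40 against 2.4% elsewhere (Fisher exact p = 0.0721). A sequence variant under 1 probe would leave a second probe of the gene without the difference. Over 48 genes with a second detected probe its difference was 0.555 times the first (bootstrap 95% interval 0.407 to 0.746), and for 22 of them under 0.5. These genes were picked by the first probe, which is also the brighter, so that a ratio below 1 can arise without a variant. For the 15 of these genes with a mean difference of at least 0.5, a limit that was not planned, the ratio was 0.762 (0.546 to 0.967), with 3 under 0.5. The second probes of Mest, Gnptg, Asns and Noa1 gave 0.935, 0.914, 0.967 and 1.00 times the first, which argues against such a variant for these 4 genes. For the 182 genes as a set the explanations cannot be told apart here. Direct and indirect effects of Rest stay open too, since the list need not hold every REST target.

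A gain of chromosome 11 in part of the knockout cells is a candidate explanation for some of these differences, and it stays open. The planned test asked for a chromosome to stand more than 0.2 from all genes, which chromosome 11, at 0.109, did not reach, while it passed the 0.1 under which no gain or loss would have been read. In the tests chosen afterwards each of 10 stretches along it was higher, from 0.0592 to 0.137, so that no single region made the difference. Against genes of like brightness elsewhere the value was 0.114, without background correction 0.116 and with median centring 0.103. Of the 182 genes 24 lie on chromosome 11, 21 of them higher in the knockout. A loss in the control cells would look the same, and no karyotype was used here.

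Whether the count for the genotype averaged over days could arise from any grouping was tested with 100 splits of the arrays within days, out of 648 possible. Only 1 of the 100, that of the labels, gave as many genes: 769, against 317 at most in the others. The split with 317 parted 3 of the days as the labels do. A split that mixes the genotypes within a day adds any real difference to the spread and so calls fewer genes. Only the rank of the labels' split, and not its distance from the other counts, therefore bears on chance. That rank argues against a grouping of these arrays with no genotype difference at all. A strong difference in part of the genes, such as the REST targets, could by itself put this split first. The rank therefore does not exclude chance for most of the 769 genes. If the arrays of a group share a culture, chance differences between cultures were not tested, nor was a difference between the lines.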
